A study of Homo sapiens with 11 samples.

How the data were processed

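The series holds 11 stranded, poly(A)-selected mRNA libraries, made with an Illumina TruSeq kit per the labels' protocols, from CCRF-CEM-GFI1-3XFLAG cells that carry a doxycycline-inducible GFI1. The deposited table gives raw read counts per gene, identified by Ensembl ID, symbol and biotype. The authors' processing notes name STAR, Subread, featureCounts and DESeq2 1.28.1, with no role or order per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands, and copies that share reads, carry that uncertainty. Every one of the 17977 listed genes reached at least 6 counts in some library, so genes below that are not seen. All table columns matched a sample by name, and 13 symbols occur on more than 1 row, which were kept apart by Ensembl ID.

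Samples were grouped by the RNP and treatment in their labels. Total counts per library ran from 17569554 to 22914324, and a fold of 1.2 could be resolved for part of the genes at that depth: in data simulated for GFI1 induction in control-RNP cells over 15173 genes, 47.8% of genes changed 1.2-fold were recovered, 68.7% of those changed 1.5-fold and 90.9% of those changed 2-fold. For the IKAROS RNP in PBS the shares were 49.3%, 68.7% and 84.8%, and for the interaction 29.9%, 55.2% and 69.7%. Pairs of libraries of one group differed by more than sampling noise, with chi-square per gene between 1.318 and 2.882, so none was counted as a repeat of another. The mitochondrial share of counts was 3.27% to 3.82%. Ribosomal protein genes took 4.50% ± 0.0346 of counts with PBS and control RNP, 4.44% ± 0.0582 with doxycycline and control RNP (SD, n = 3 each), 4.34% ± 0.0368 with PBS and IKAROS RNP (SD, n = 2) and 4.17% ± 0.0781 with doxycycline and IKAROS RNP (SD, n = 3).

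Genes were kept with edgeR's filterByExpr (15173 genes), scaled by TMM, and tested with edgeR 4.0.16's quasi-likelihood test in R 4.3.3 with 1 mean per group over all 11 libraries, so that groups of 2 and 3 share 1 estimate of spread. The common biological coefficient of variation was 2.46%. P-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, and log2 values used a prior count of 2. The 5 comparisons were doxycycline over PBS in control-RNP cells, IKAROS RNP over control RNP in PBS, doxycycline over PBS in IKAROS-RNP cells, IKAROS RNP over control RNP in doxycycline, and the difference of the inductions (interaction).

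Before the data were examined, 24 gene lists with 535 distinct genes were fixed from textbook knowledge, and 444 of these genes were in the table. Some genes belong to several lists, so the lists are not fully separate. GFI1 and IKZF1 were left out of the lists. Lists were tested with limma 3.58.1's camera at a preset correlation of 0.01, repeated with an estimated correlation and with fry, and adjusted over the 24 lists. Gene positions came from GENCODE v44 on GRCh38, matched by Ensembl ID for 15115 of the 15173 tested genes, since the table gives no coordinates. GC content came from the longest transcript of each gene in that annotation.

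The genes to name were also fixed beforehand. GFI1 and IKZF1 came first. For the first 2 comparisons the 10 largest rises and 10 largest falls followed, and for the others the 5 largest each way, among called genes with a mean log2 CPM of at least 3 and, except for the interaction, no overlap between the libraries compared. From each list up to 2 members each way with the smallest adjusted p were added.

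Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter and a filter at a mean log2 CPM of 3, DESeq2 1.42.0, limma-voom, a fit with only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. A GC correction of each library, protein-coding genes alone, and averages over both backgrounds were added after seeing the data. Ranges of a gene's adjusted p over the alternatives take the value of each alternative's own test, DESeq2 and limma-voom included. For comparisons that share control libraries, unchanged groups were simulated 20 times against the same controls. Gene calls, the list test, the slope and the GC correction were tested on simulated counts first. The lists simulated unchanged gave 0 calls, but genes were simulated independently, so this does not test the effect of correlation between list members. A simulated slope of 1.3 was recovered as 1.297. With simulated GC trends, 369 of the unchanged genes among 15173 were called for GFI1 induction in control-RNP cells before the correction and 10 after. The share of 2-fold genes recovered went from 86.4% to 80.3%. All 11 libraries and all listed genes were used, and doxycycline without the GFI1 cassette was not analysed here.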

Results

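Messenger RNA was sequenced from CCRF-CEM-GFI1-3XFLAG, a derivative of the human T cell acute lymphoblastic leukaemia line CCRF-CEM in which doxycycline induces the transcriptional repressor GFI1. GFI1 mRNA was already present without doxycycline. Cells had received a control CRISPR ribonucleoprotein (RNP) or one directed at IKAROS, the lymphoid transcription factor encoded by IKZF1, and were then given 1 µM doxycycline or PBS for 24 h. The 11 libraries made 4 groups: 3 with PBS and control RNP, 3 with doxycycline and control RNP, 2 with PBS and IKAROS RNP, and 3 with doxycycline and IKAROS RNP. Gene counts summed to between 17569554 and 22914324 per library, and 15173 of the 17977 listed genes had enough counts to be tested. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given as CPM, counts scaled to a common library size. The design asks what induced GFI1 changes, what the IKAROS RNP changes, and whether the response to GFI1 differs when IKAROS has been targeted. GFI1 induction stands below for doxycycline over PBS, and effects of doxycycline itself cannot be told apart from those of GFI1. Changes with the IKAROS RNP stand for IKAROS RNP over control RNP. The labels give no batch, so in these contrasts a batch that follows the RNP cannot be told apart from the RNP.

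GFI1 (ENSG00000162676, chromosome 1, 92473043 to 92486925 in GRCh38) rose in every doxycycline library. Its mean was 86.1 ± 1.58 CPM with PBS and 157 ± 2.59 with doxycycline in control-RNP cells (SD, n = 3 each). In IKAROS-RNP cells it was 78.2 ± 0.946 with PBS (SD, n = 2) and 169 ± 7.34 with doxycycline (SD, n = 3). Between the RNPs, GFI1 differed by -0.14 ± 0.04 in PBS (SE; adjusted p = 0.0386) and by 0.10 ± 0.03 in doxycycline (SE; adjusted p = 0.0356, edgeR quasi-likelihood test, Benjamini-Hochberg), and each call was lost in 8 of 21 alternatives. By that edgeR test the first call (GFI1, IKAROS RNP effect in PBS) had an adjusted p of 0.0667 and 0.0828 without PBS control-RNP replicates 1 and 2. It was also lost without PBS IKAROS-RNP replicate 1 or 2. Its lowest adjusted p over the alternatives, each with its own test, was 0.00568. For the second call (GFI1, IKAROS RNP effect in doxycycline) the adjusted p ranged from 0.00128 to 0.169 over the alternatives, each with its own test. By edgeR it was 0.165, 0.0786 and 0.0574 without doxycycline control-RNP replicates 1, 2 and 3, and 0.162 and 0.169 without doxycycline IKAROS-RNP replicates 1 and 3. The counts do not separate transcripts of the introduced cassette from those of the cell's own GFI1 gene. IKZF1 (ENSG00000185811, chromosome 7, 50304068 to 50405101) had 402 ± 11.5 CPM with PBS and control RNP and 417 ± 8.13 with PBS and IKAROS RNP, a log2 fold change of 0.06 ± 0.03 (SE) that did not pass (adjusted p = 0.311, edgeR quasi-likelihood test, Benjamini-Hochberg). With doxycycline the same contrast gave -0.02 ± 0.03 (SE; adjusted p = 0.71 by the same edgeR test). A CRISPR edit can disable a protein without lowering its mRNA, so these levels do not check the edit in either direction. With doxycycline in IKAROS-RNP cells IKZF1 fell by 0.13 ± 0.03 (SE; adjusted p = 0.00128, edgeR quasi-likelihood test, Benjamini-Hochberg), with 0.0598 without PBS IKAROS-RNP replicate 1 and a range over all alternatives of 0.000376 to 0.0598.

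**Figure D1:**
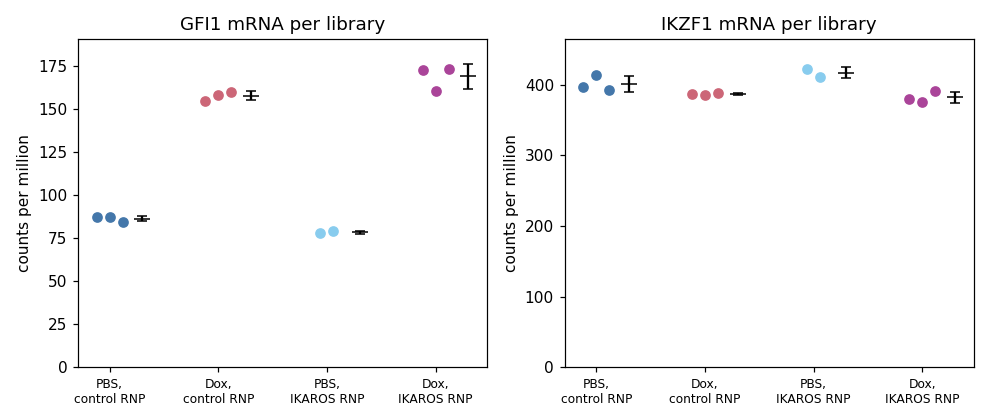
GFI1 and IKZF1 mRNA in CPM (vertical axis, from 0) in each library, by group; points are libraries, and the bar beside them is the mean with its SD. GFI1 lies between 77.55 and 87.1 in the PBS libraries and between 154.5 and 173.17 in the doxycycline libraries, while IKZF1 stays between 376.47 and 423.05 in all 11.

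The ranking that follows holds only for called genes with a mean log2 CPM of at least 3 and no overlap between the libraries compared. GFI1 induction in control-RNP cells raised FGF17, a fibroblast growth factor, by a log2 fold change of 2.30 ± 0.09 (SE), from 5.32 to 26.0 CPM. PTCRA, which encodes the pre-T cell receptor alpha chain, rose by 1.52 ± 0.10, and IL2RB, the beta chain shared by the interleukin 2 and 15 receptors, by 1.48 ± 0.07. The fibroblast growth factor receptor FGFR3 rose by 1.48 ± 0.06, the desmosomal protein gene PKP1 by 1.53 ± 0.06 and FAM30A by 1.48 ± 0.15. LZTS3, TNNT1, GLIPR2 and BEGAIN followed, with rises of 2.43-fold, 2.42-fold, 2.35-fold and 2.30-fold. The largest falls among genes of that level were smaller: SOSTDC1, a secreted BMP and WNT antagonist, fell by 1.04 ± 0.09, the sodium channel gene SCN3A by 0.86 ± 0.09, and NRN1 by 0.81 ± 0.04. ARHGEF11, LPAR6, SIPA1L2, CLEC2B, KCTD12 and RGMB fell by 0.81, 0.78, 0.77, 0.76, 0.72 and 0.72, and the T cell transcription factor RUNX3 fell by 0.76 ± 0.08. Of these 20 genes, CLEC2B had the largest adjusted p, 1.44e-08 (edgeR quasi-likelihood test, Benjamini-Hochberg).

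Over all tested genes, 1507 were higher and 1613 lower with doxycycline at the 0.05 threshold (1651 and 1431 with upper-quartile scaling), with a median change among the calls of 1.16-fold. Rises of at least 2-fold numbered 167 and falls 20. Fold changes followed GC content across genes (Spearman 0.377 over 11834 genes, which are not independent replicates); with a GC correction added after seeing the data, 3502 genes were called, 2156 of 3116 calls were kept and 46 changed sign.

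Among the gene lists fixed beforehand, 26 genes of ribosome biogenesis, many of them MYC targets, had the smallest camera p: 18 fell, among them NOLC1 by 0.22 and DDX21 by 0.20, and none rose (22 fell adjusted over the list alone). Its camera test gave an adjusted p of 1.61e-08, and 0.0122 with an estimated correlation. Of 24 migration and adhesion genes, 11 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.000375, and adjusted p = 0.0291 with an estimated correlation). The sphingosine phosphate receptor gene S1PR1, needed for lymphocyte egress, fell by 0.65 ± 0.06 and the integrin gene ITGA6 by 0.48 ± 0.03, whereas ITGAL rose by 0.42 ± 0.04.

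Glycolysis genes fell in 13 of 24 cases and rose in 3 (the same counts adjusted over the list alone). Pyruvate kinase PKM fell by 0.33 ± 0.02 and hexokinase HK2 by 0.38 ± 0.04, while the lactate transporter SLC16A3 rose by 0.77 ± 0.08 and ENO2 by 0.40 ± 0.04. The camera adjusted p of 0.00283 became an adjusted p of 0.293 with an estimated correlation. Of 23 genes of the ATF4 stress response, 11 fell, including SLC7A5 by 0.24 and PSAT1 by 0.23, and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.00465, and adjusted p = 0.0866 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 23 cases and rose in 1 (11 and 1 adjusted over the list alone), with HMGCS1 down by 0.26 ± 0.03 and TM7SF2 up by 0.76 ± 0.08. That list had a camera adjusted p of 0.0138, an adjusted p of 0.0866 with an estimated correlation, and a camera adjusted p of 0.0742 without PBS control-RNP replicate 1.

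Mitosis genes rose in 8 of 26 cases and fell in 1 (9 and 1 adjusted over the list alone), with CENPE up by 0.17 ± 0.03, UBE2C up by 0.15 ± 0.03 and KIF11 down by 0.21 ± 0.03. The camera adjusted p of 0.0271 became an adjusted p of 0.642 with an estimated correlation. It was 0.141 without PBS control-RNP replicate 1, 0.0505 without PBS control-RNP replicate 3 and 0.114 without doxycycline control-RNP replicate 3. Of 30 transcription factors of the T lineage and of T cell leukaemia, 14 fell and 5 rose (15 and 6 adjusted over the list alone; camera adjusted p = 0.0058, and adjusted p = 0.167 with an estimated correlation). BACH2 fell by 0.70 ± 0.05 and IKZF2 by 0.42 ± 0.04. ZBTB7B, which directs CD4 T cell fate, rose by 2.01 ± 0.17 from a low level of 1.32 CPM, and TCF7 rose by 0.19 ± 0.02.

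Other T cell genes moved in both directions. In the NOTCH list, 2 of 16 genes rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.874): NOTCH3 rose from 27.1 ± 2.02 to 60.3 ± 1.57 CPM (SD, n = 3 each), while the NOTCH target HES1 fell by 0.26 ± 0.04. Of 27 T cell receptor and surface genes, 10 rose and 4 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.628). CD7 rose by 0.57 ± 0.04 and CD5 by 0.44 ± 0.04, whereas CD1C fell by 0.56 ± 0.04 and TRAT1 by 0.55 ± 0.04. Of the 13 tested genes reported elsewhere as repressed by GFI1, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.628), with ID2 up by 0.71 ± 0.11 and IL7R down by 0.32 ± 0.05.

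**Figure D2:**
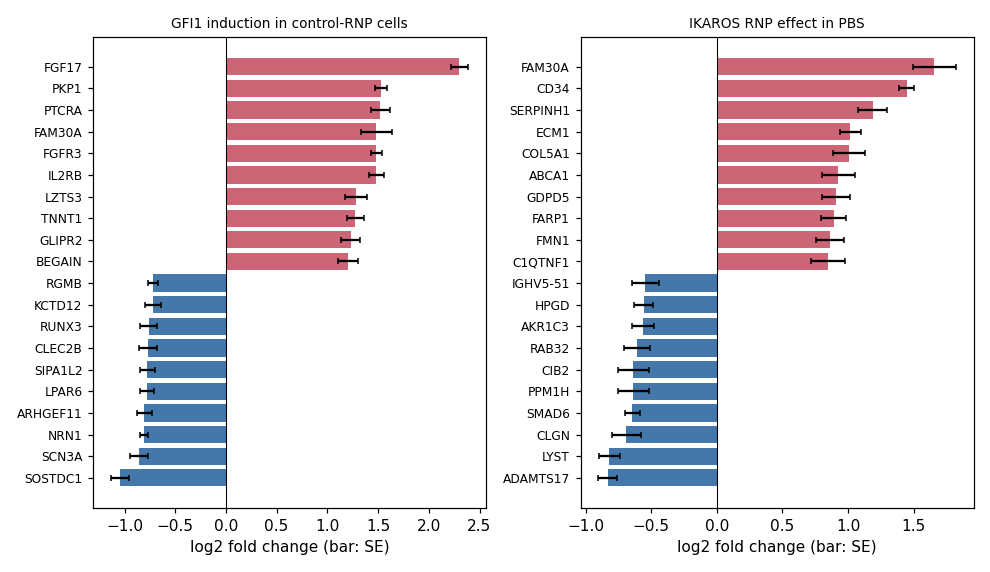
Log2 fold change (horizontal axis) with its SE for the 10 largest rises and 10 largest falls among well expressed genes, for doxycycline over PBS in control-RNP cells (left) and for IKAROS RNP over control RNP in PBS (right). On the left the rises reach 2.30 (FGF17) and the falls -1.04 (SOSTDC1); on the right they reach 1.66 (FAM30A) and -0.83 (ADAMTS17).

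The IKAROS RNP in PBS raised CD34, the haematopoietic progenitor surface marker, by a log2 fold change of 1.45 ± 0.06 (SE), from 28.5 ± 3.21 (SD, n = 3) to 78.3 ± 2.37 CPM (SD, n = 2). FAM30A rose by 1.66 ± 0.16, the collagen chaperone gene SERPINH1 by 1.19 ± 0.11, ECM1 by 1.02 ± 0.08 and the collagen gene COL5A1 by 1.01 ± 0.12. The cholesterol exporter gene ABCA1 rose by 0.93 ± 0.13, and GDPD5, FARP1, FMN1 and C1QTNF1 by 0.91, 0.89, 0.86 and 0.85. ADAMTS17 fell by 0.83 ± 0.07, and LYST, which acts in lysosomal trafficking, fell by 0.82 ± 0.08. CLGN fell by 0.69 ± 0.11, the BMP signalling inhibitor SMAD6 by 0.64 ± 0.06, PPM1H by 0.64 ± 0.12 and CIB2 by 0.64 ± 0.12. RAB32, AKR1C3, HPGD and IGHV5-51 fell by 0.61, 0.56, 0.56 and 0.54; IGHV5-51 belongs to a family of similar genes whose reads can be shared, so its value is uncertain. The largest adjusted p of these 20 genes was 0.000428, for IGHV5-51 (edgeR quasi-likelihood test, Benjamini-Hochberg). Without PBS IKAROS-RNP replicate 2 the adjusted p of PPM1H was 0.0558 and that of CIB2 0.0568 by the same edgeR test; over all alternatives the values ranged from 3.82e-05 to 0.0558 and from 0.000105 to 0.0568.

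Of 24 genes reported elsewhere as IKAROS targets, 9 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00148, and adjusted p = 0.0605 with an estimated correlation). The recombinase gene RAG1 fell by 0.40 ± 0.03, from 912 to 693 CPM, and CD4 fell by 0.48 ± 0.04, whereas CD44 rose by 0.26 ± 0.04. Migration and adhesion genes rose in 7 of 24 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000397, adjusted p = 0.0484 with an estimated correlation, and adjusted p = 0.0671 with an estimated correlation after the GC correction). ITGA6 rose by 0.56 ± 0.03 and KLF2, a regulator of T cell quiescence and trafficking, by 1.54 ± 0.21 from 1.42 CPM, while ITGA4 fell by 0.19 ± 0.03. Of 23 genes of IL7, cytokine and JAK-STAT signalling, 6 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00346, and adjusted p = 0.0605 with an estimated correlation). SOCS2 was higher by 0.53 ± 0.13 and IL21R by 0.38 ± 0.09, yet SOCS2 had an adjusted p of 0.0782 without PBS IKAROS-RNP replicate 1 and IL21R 0.0981 without replicate 2 (edgeR quasi-likelihood test, Benjamini-Hochberg). Over all alternatives these p-values ranged from 0.00102 to 0.0782 and from 0.0046 to 0.0981.

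Cholesterol synthesis genes fell in 5 of 23 cases and none rose (the same counts adjusted over the list alone), among them HMGCS1 by 0.24 ± 0.04 and MSMO1 by 0.26 ± 0.05. The camera adjusted p was 0.00916, the adjusted p with an estimated correlation 0.0605, and the camera adjusted p without PBS IKAROS-RNP replicate 2 was 0.0628. Of 13 mitochondrially encoded genes, 4 fell and none rose (6 fell adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.584 with an estimated correlation). That camera adjusted p was 0.2 without PBS control-RNP replicate 3 and 0.113 without PBS IKAROS-RNP replicate 2, and 0.0506 after the GC correction. In the list of T lineage transcription factors 5 of 30 rose and 2 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.16), with RUNX3 up by 0.70 ± 0.08 and ID3 up by 0.47 ± 0.07. Of 27 T cell receptor and surface genes 4 rose, including CD1C by 0.32 ± 0.04 and TRBC2 by 0.20 ± 0.03, and 3 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.555). The NOTCH list had 1 riser and 3 fallers among 16 (1 and 4 adjusted over the list alone, camera adjusted p = 0.196). NOTCH3 was at -0.28 ± 0.07, a call lost without PBS IKAROS-RNP replicate 2. Its lowest adjusted p over the alternatives, each with its own test, was 0.00116.

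The IKAROS RNP in PBS gave 595 higher and 504 lower genes. Processed pseudogenes, intronless copies of other genes, made up 82 of the lower and 2 of the higher genes, and 60 of the 90 falls of at least 2-fold. All 642 tested processed pseudogenes had a median log2 fold change of -0.35 here and of -0.35 with the IKAROS RNP in doxycycline. Among protein-coding genes 553 were higher and 397 lower, with 47 rises and 20 falls of at least 2-fold. The total of 1099 was 660 without PBS IKAROS-RNP replicate 1, 449 without replicate 2, 608 by DESeq2 and 725 with a stricter level filter. Upper-quartile scaling turned the split to 477 higher and 655 lower.

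**Figure D3:**
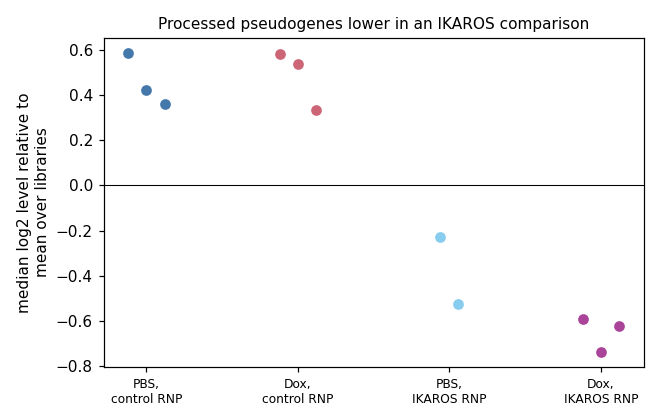
Median log2 level, relative to the mean over all libraries, of the 196 processed pseudogenes called lower in either IKAROS comparison (vertical axis), with 1 point per library, by group. The 6 control-RNP libraries lie between 0.334 and 0.586 and the 5 IKAROS-RNP libraries between -0.737 and -0.227; the genes were chosen for this difference.

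**Figure D4:**
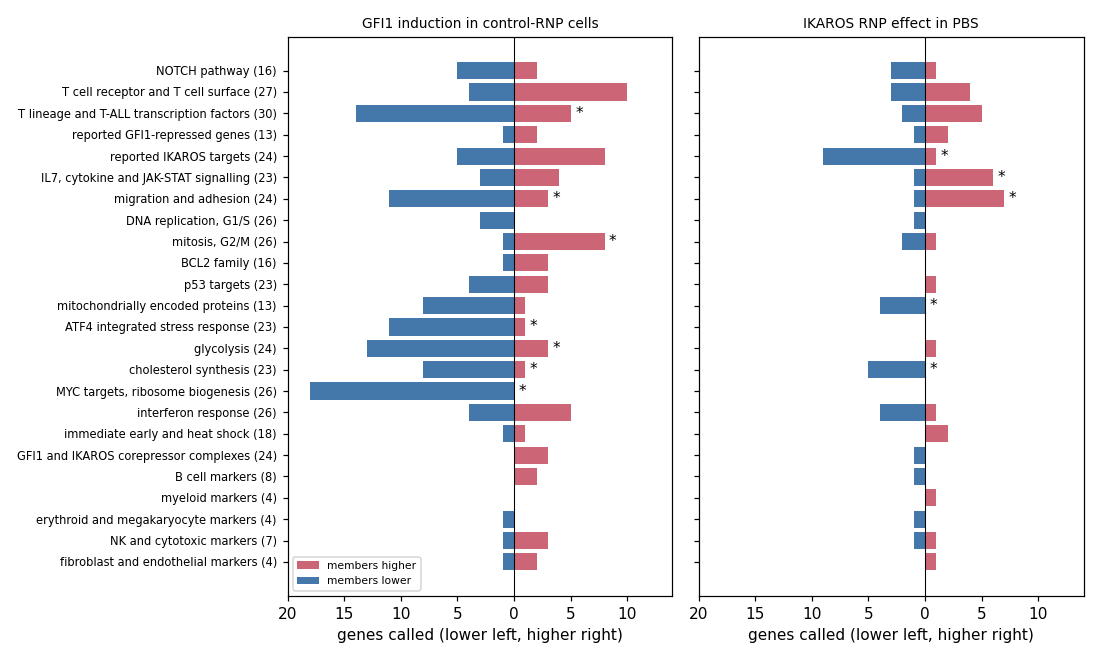
Members of each gene list called higher (right of 0) or lower (left of 0) for GFI1 induction in control-RNP cells and for the IKAROS RNP in PBS; the number of tested members is in brackets and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The longest bar is that of ribosome biogenesis genes, of which 18 fell under GFI1 induction.

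GFI1 induction in IKAROS-RNP cells moved many of the genes seen in control-RNP cells. FGF17 rose by a log2 fold change of 2.90 ± 0.10 (SE), PTCRA by 1.97 ± 0.11, IL2RB by 1.91 ± 0.08, FGFR3 by 1.79 ± 0.06 and the erythrocyte membrane protein gene DMTN by 1.84 ± 0.11. ARHGEF11 fell by 1.39 ± 0.08, SCN3A by 1.29 ± 0.10, SOSTDC1 by 1.21 ± 0.09, RUNX3 by 1.16 ± 0.08 and LPAR6 by 1.13 ± 0.08; the largest adjusted p of these 10 genes was 2.1e-13, for SCN3A (edgeR quasi-likelihood test, Benjamini-Hochberg). Ribosome biogenesis genes fell in 23 of 26 cases (also 23 adjusted over the list alone; camera adjusted p = 1.03e-09, and adjusted p = 0.00821 with an estimated correlation). Migration genes fell in 14 of 24 cases and rose in 2 (the same counts adjusted over the list alone), with S1PR1 down by 1.03 ± 0.07, a camera adjusted p of 1.56e-05 and an adjusted p of 0.0138 with an estimated correlation. Glycolysis genes fell in 18 of 24 cases and rose in 2 (18 and 3 adjusted over the list alone), with PKM down by 0.49 ± 0.03 and HK2 down by 0.67 ± 0.05. That list had a camera adjusted p of 1.31e-05 and an adjusted p of 0.122 with an estimated correlation. T lineage transcription factors fell in 16 of 30 cases and rose in 5 (16 and 6 adjusted over the list alone; camera adjusted p = 0.000879, and adjusted p = 0.109 with an estimated correlation), with BACH2 down by 0.98 ± 0.05. ATF4 stress response genes fell in 11 of 23 cases (12 fell and 3 rose adjusted over the list alone; camera adjusted p = 0.00682, and adjusted p = 0.109 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 23 cases and rose in 1 (the same counts adjusted over the list alone), but the list was not called here (camera adjusted p = 0.0567). DNA replication genes fell in 6 of 26 cases (also 6 adjusted over the list alone; camera adjusted p = 0.0289, and adjusted p = 0.122 with an estimated correlation), and the camera value was 0.0836 without PBS IKAROS-RNP replicate 1 and 0.0752 without doxycycline IKAROS-RNP replicate 3. Mitosis genes rose in 7 of 26 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0256, and adjusted p = 0.678 with an estimated correlation). Their camera value was 0.0656 without PBS IKAROS-RNP replicate 1, and 0.0738 and 0.0533 without doxycycline IKAROS-RNP replicates 2 and 3.

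For GFI1 induction in IKAROS-RNP cells, 1774 genes were higher and 2020 lower (2082 and 1697 with upper-quartile scaling), and the total of 3794 was 2454 without PBS IKAROS-RNP replicate 2. Across genes the fold changes had a Spearman correlation with GC content of 0.207, and after the GC correction 3031 of 3791 calls were kept and 45 changed sign.

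The IKAROS RNP in doxycycline again raised FAM30A (1.48 ± 0.09, log2 fold change with SE), SERPINH1 (1.27 ± 0.09) and COL5A1 (0.95 ± 0.08). CD34 rose from 31.4 ± 0.75 to 76.3 ± 2.29 CPM and GDPD5 from 7.91 ± 0.547 to 16.5 ± 0.497 CPM (SD, n = 3 each). PPM1H fell by 0.75 ± 0.11, SMAD6 by 0.69 ± 0.05, the potassium channel gene KCNA3 by 0.64 ± 0.08, the lysosomal protease gene LGMN by 0.64 ± 0.08 and CORO2A by 0.63 ± 0.07. The largest adjusted p of these 10 genes was 3.36e-06, for PPM1H (edgeR quasi-likelihood test, Benjamini-Hochberg). Reported IKAROS targets fell in 10 of 24 cases and rose in 1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.122 with an estimated correlation), with CD4 down by 0.49 ± 0.04 and RAG2 down by 0.44 ± 0.05. Genes of IL7, cytokine and JAK-STAT signalling rose in 7 of 23 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.107 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 23 cases and rose in 1 (7 and 1 adjusted over the list alone), with HMGCS1 down by 0.28 ± 0.03, and ribosome biogenesis genes fell in 3 of 26 (2 adjusted over the list alone). Their camera adjusted p-values were 0.0156 and 0.00525, each with an adjusted p = 0.107 with an estimated correlation. DNA replication genes fell in 6 of 26 cases (also 6 adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.107 with an estimated correlation), and the camera value was 0.0681 without doxycycline IKAROS-RNP replicate 3. Migration and adhesion genes, raised by the RNP in PBS, had 5 higher and 4 lower of 24 here (6 and 4 adjusted over the list alone; median -0.004; camera adjusted p = 0.569). Of 13 mitochondrially encoded genes 1 was higher and none lower (the same adjusted over the list alone; camera adjusted p = 0.491). Of the 2063 genes called, 960 were higher and 1103 lower, and DESeq2 called 1201. Processed pseudogenes were 176 of the lower and 1 of the higher genes, and 144 of the 197 falls of at least 2-fold. Among protein-coding genes 899 were higher and 846 lower.

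The response to doxycycline differed between IKAROS-RNP and control-RNP cells for 46 genes, tested as the interaction. RAG1 rose by 0.25 in control-RNP cells and by 0.49 in IKAROS-RNP cells, a difference of 0.24 ± 0.04 (SE; adjusted p = 0.000273, edgeR quasi-likelihood test, Benjamini-Hochberg). RAG1 already differed between the RNPs in PBS, at -0.396 for IKAROS RNP over control RNP. CRYBG1 fell by 0.58 and by 0.97, a difference of -0.39 ± 0.06, and USP13 fell by 0.22 and by 0.68, a difference of -0.46 ± 0.08. These 3 were the only ones of the 18 named interaction genes whose call held in every setting and without each library. VIM, outside the naming rule and named after its values were seen, had the smallest adjusted p of the 46. It fell by 0.60 and by 0.98, a difference of -0.38 (adjusted p = 9.93e-08, edgeR quasi-likelihood test, Benjamini-Hochberg). Its call was not followed over the alternatives. GFI1 itself rose further in IKAROS-RNP cells, by 0.24 ± 0.05 (adjusted p = 0.0344, edgeR quasi-likelihood test, Benjamini-Hochberg). That call was lost without PBS IKAROS-RNP replicate 1 or 2. Its lowest adjusted p over the alternatives, each with its own test, was 0.000606. By edgeR the GFI1 difference had an adjusted p of 0.056 without PBS control-RNP replicate 2, and of 0.108, 0.0769 and 0.0653 without doxycycline control-RNP replicates 1, 2 and 3. The edgeR value was 0.102 and 0.114 without doxycycline IKAROS-RNP replicates 1 and 3.

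Of the 45 interaction genes other than GFI1, all were called for induction in IKAROS-RNP cells and 41 in control-RNP cells. The fold change had the same sign in both backgrounds and was larger in IKAROS-RNP cells for 42 of them, and 3 had opposite signs: MT-ND6, and AL353622.1 and CD164, which are named here after their values were seen. The lists of migration genes (camera adjusted p = 0.000242, adjusted p = 0.0464 with an estimated correlation, and adjusted p = 0.0637 with an estimated correlation after the GC correction) and of glycolysis genes (0.000242, and adjusted p = 0.295 with an estimated correlation) had lower interaction values than other genes. Only S1PR1 of 24 migration genes and PKM and HK2 of 24 glycolysis genes were called singly (4 and 5 adjusted over the list alone). Mitochondrially encoded genes had higher values (camera adjusted p = 0.00142, and adjusted p = 0.611 with an estimated correlation), with 1 of 13 called, MT-ND6, and 8 adjusted over the list alone. Under induction 8 of the 13 fell and 1 rose in control-RNP cells (median -0.113). In IKAROS-RNP cells 6 rose and 2 fell (median 0.077). Neither induction moved the list as a whole (camera adjusted p = 0.141 and 0.736). MT-ND6 lies on the minus strand, and the strand setting of the counting is not given, so its value may include reads of the opposite strand. Ribosome biogenesis genes had lower values (camera adjusted p = 0.0112, and adjusted p = 0.222 with an estimated correlation), with 0 of 26 called by edgeR; the camera value was 0.0798 without doxycycline control-RNP replicate 1 and 0.105 without PBS IKAROS-RNP replicate 2. T lineage transcription factors also had lower values (camera adjusted p = 0.0156, and adjusted p = 0.295 with an estimated correlation), with 1 of 30 called, ERG, and 5 adjusted over the list alone. That camera value was 0.0901 without PBS control-RNP replicate 3, 0.0602 without doxycycline control-RNP replicate 3, 0.109 without PBS IKAROS-RNP replicate 2 and 0.0909 without doxycycline IKAROS-RNP replicate 2. The count of 46 was 29 by DESeq2. It was 23 without doxycycline control-RNP replicate 2, 26 without its replicate 3, 18 and 13 without PBS IKAROS-RNP replicates 1 and 2, 24 and 25 without doxycycline IKAROS-RNP replicates 1 and 3, and 105 after the GC correction.

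**Figure D5:**
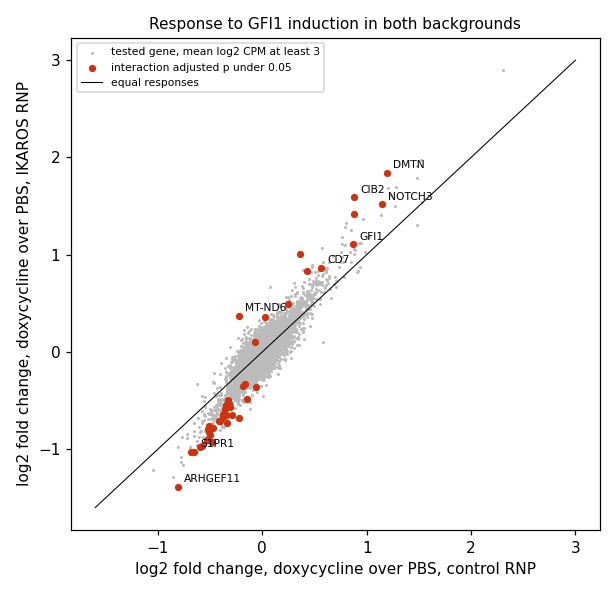
Log2 fold change of doxycycline over PBS in control-RNP cells (horizontal) and in IKAROS-RNP cells (vertical) for the 9700 tested genes with a mean log2 CPM of at least 3; red points passed the interaction test and the line marks equal responses. GFI1 lies at 0.87 and 1.11, and most red points lie farther from 0 on the vertical than on the horizontal axis.

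The responses to GFI1 induction in the control-RNP and IKAROS-RNP backgrounds, which share no library, had a Pearson correlation of 0.673 across 15173 genes and 0.884 across the 9700 genes with a mean log2 CPM of at least 3; genes are not independent replicates. In simulations with no effect the correlation was -0.0025 (median of 20, range -0.04 to 0.032). A value near 0 is built into those simulations, which hold no shared library and no GC trend. After the GC correction the correlation was 0.655 across tested genes with a GC value. Of the 2249 genes called in both backgrounds, FGF17 and S1PR1 among them, 2247 moved the same way. Among genes with that mean level, GFI1 left out, the slope of the IKAROS-RNP on the control-RNP response, allowing for error in both, was 1.322, and it lay between 1.24 and 1.379 when 1 library at a time was left out.

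Genes called both for GFI1 induction in control-RNP cells and for the IKAROS RNP in PBS numbered 444. FAM30A was higher in both, and ITGA6, S1PR1 and CD44 were lower with GFI1 and higher with the IKAROS RNP. By direction, 142 were higher in both (59.1 if the lists were independent), 84 lower in both (53.6), 83 higher with GFI1 and lower with the RNP (50.1), and 135 the reverse (63.3). Both comparisons use the same 3 PBS control-RNP libraries, too few to split. Sharing them pushes both fold changes the same way (simulated correlation 0.447), so part of the same-direction excess may come from these controls. The excess in opposite directions is not explained by them. The counts for independent lists, here and below, take every tested gene as equally likely to be called. Whether differences in level between genes add to the excess was not tested. Unchanged groups simulated against the shared controls had a median of 0 calls in common (highest 1 of 20 simulations). With few calls to share, these simulations do not measure what the shared controls add between lists of this length. The covariance of the fold changes was 0.00116 against 0.00154 simulated, a difference of -0.000372. The count of 444 was 252 by DESeq2, and 282 and 223 without PBS IKAROS-RNP replicates 1 and 2.

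GFI1 induction in control-RNP cells and the IKAROS RNP in doxycycline, which share the 3 doxycycline control-RNP libraries, had 791 called genes in common. Of these, 311 were higher in both (95.3 if the lists were independent), 273 lower in both (117.3), 96 higher with GFI1 and lower with the RNP (109.6), and 111 the reverse (102.1). The covariance of the fold changes was 0.00489 against -0.00148 simulated, a difference of 0.00638, and these controls are also too few to split. By construction, the RNP effect in doxycycline equals the RNP effect in PBS plus the interaction. The GFI1 response was larger in IKAROS-RNP cells (slope 1.322), so the shared direction here is not separate from that difference. Averages of each effect over both backgrounds, added after seeing the data, had 1437 called genes in common. There 496 were higher in both (228.5 if independent), 445 lower in both (262), 214 higher with GFI1 and lower with the RNP (242.2), and 282 the reverse (247.1). These averages contain the interaction as well, so the same limit holds for them.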

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

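The tests of a batch that follows the RNP and of doxycycline itself were chosen only after the result was seen. So were the tests of few counts behind the lower pseudogenes and the 2-fold rises. The values over all tested pseudogenes and the simulation of scaled responses were also added then. The others were chosen before their own result, but the GC test uses a correction added after seeing the data.

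The response to doxycycline differed between IKAROS-RNP and control-RNP cells, by the interaction test, for 46 genes. Among those named, the log2 fold change in IKAROS-RNP minus that in control-RNP cells was 0.71 for CIB2, 0.65 for DMTN, 0.65 for the metallothionein gene MT2A, 0.60 for MT-ND6 and 0.54 for MGAT4B. It was -0.58 for ARHGEF11, -0.46 for USP13, -0.45 for PLCL2, -0.40 for SPRY1 and -0.39 for CRYBG1. From the gene lists, the difference was 0.37 for NOTCH3, 0.30 for CD7 and 0.24 for RAG1, and -0.35 for ERG, -0.38 for S1PR1, -0.16 for PKM and -0.29 for HK2. For GFI1 itself, which is in no list, it was 0.24. The calls of USP13, CRYBG1 and RAG1 held in every setting tried; those of the other 15 were each lost in at least 1.

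GFI1 induction moved genes further in IKAROS-RNP than in control-RNP cells, with a slope of 1.322 across genes. By construction the interaction is the RNP effect in doxycycline minus that in PBS, so a gap in PBS can appear as a larger response. With the IKAROS RNP in PBS, RAG1 (-0.396), NOTCH3 (-0.282) and DMTN (-0.493), which induction raised, were lower. S1PR1 (0.278), which it lowered, was higher, while MT-ND6 (-0.432) moved as under induction in control-RNP cells. Not all interaction genes were compared this way. Unequal depth is argued against: with every library thinned to the same total of 17569554 counts the slope was 1.318. The larger rise of GFI1 itself is a candidate explanation, since the ratio of the GFI1 log2 fold changes was 1.275 (from a GFI1 difference between the RNPs of -0.14 in PBS and 0.10 in doxycycline, calls that were each lost in 8 of 21 alternatives), and after scaling the control-RNP response by that ratio 1 of the 45 interaction genes, MT-ND6, still passed. Their median absolute difference went from 0.31 (SE 0.066) to 0.193 (SE 0.074), so the calls ended partly because the gap shrank and partly because its error grew; all 45 kept their sign and 37 had an unadjusted p under 0.05, on genes picked for the difference. With responses simulated at exactly that ratio, 6 to 29 interaction calls appeared in 10 simulations (median 14, of which a median of 6.5 kept an unadjusted p under 0.05 after scaling), fewer than the 46 seen, so an effect of the IKAROS RNP on the response beyond the larger rise of GFI1 stays open. Scaling by the slope of 1.322, computed with GFI1 left out, also left 1 of the 45 called. The loss of calls under scaling is therefore not particular to the GFI1 ratio.

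Processed pseudogenes were lower in IKAROS-RNP than in control-RNP libraries: all 642 tested had a median log2 fold change of -0.35 in PBS and -0.35 in doxycycline, and the 196 called lower in either comparison, chosen for their fall, had -1.002 and -1.41. Few counts per gene are argued against as the whole cause, since other genes drawn at the level of all 642 had a median of -0.028 over both treatments (-0.066 to 0.013 in 100 draws) against -0.323 for the pseudogenes, with 20 to 44 of the drawn genes called lower against 196. Lower expression of their parent genes is argued against as the whole cause, since the parents found for 142 of the called pseudogenes had a median of -0.067 and those found for 432 of all tested ones -0.056. A library or sequencing batch that follows the RNP cannot be told apart from an effect of the RNP, because the labels give no batch: in the median of the called pseudogenes the lowest control-RNP library lay 0.561 above the highest IKAROS-RNP library, and over all 642 the libraries lay at 0.135 to 0.239 and -0.247 to -0.062. For doxycycline over PBS, all 642 had a median of -0.087 in IKAROS-RNP cells (22 lower, 3 higher) and -0.04 in control-RNP cells (6 lower, 4 higher). The 196, chosen partly for a low level with doxycycline and IKAROS RNP, had -0.309 and 0.026. A batch that follows only the RNP does not account for a difference by treatment, and 0 of the 642 were called for the interaction. The labels' protocol includes a DNase step, and no test here bears on residual genomic DNA.

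Rises of at least 2-fold outnumbered falls under GFI1 induction in control-RNP cells, 167 against 20. A GC trend between libraries is argued against as the whole cause, since 9.62 rises per fall remained after GC correction (154 against 16), although the slope of level on GC content lay between -0.086 and -0.0059 log2 per 10 percentage points in the PBS libraries and between 0.014 and 0.058 in the doxycycline libraries. Few counts per gene are argued against as the whole cause as well, since among genes with a mean log2 CPM of at least 3 there were 14 rises and 1 fall, a ratio of 14; this rests on 15 genes, and the other 153 rises and 19 falls lay below that level. Doxycycline itself cannot be told apart from GFI1, because every induced library received it; the ATF4 list, which a mitochondrial stress from doxycycline could raise, had a median of -0.072 (-0.125 after GC correction). GFI1 acting through genes it represses stays open and was not tested.

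The other splits of the samples are too few for a share under 0.05: the 6 libraries of GFI1 induction in control-RNP cells make 10 splits, with 3120 genes called in the real one, 1 of 10, and at most 0 in the others by edgeR (4792 and at most 1377 at an unadjusted p under 0.05). The 6 libraries of the IKAROS RNP in doxycycline also make 10, with 2063 in the real one, 1 of 10, and at most 0 in the others by edgeR (3932 and at most 771 at an unadjusted p under 0.05).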

How the results depend on the processing

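The GC correction, the protein-coding subset and the averages over backgrounds were chosen after seeing the data; the other alternatives were fixed before. Named calls kept their direction in every alternative except IKZF1 for the IKAROS RNP in doxycycline, not called at -0.02, which was 0.0027 after the GC correction; the cause was not tested. Of all called genes, 46 and 45 changed sign after GC correction for GFI1 induction in control-RNP and IKAROS-RNP cells, and 0 in the other comparisons. Of the named results, 44 of 319 lost their call by DESeq2, 12 of 272 with the level filter, 16 of 322 after GC correction, 9 of 322 with upper-quartile scaling and 240 of 3542 without 1 library. Of called named genes, 70 of 84 for GFI1 induction in control-RNP cells and 36 of 64 for the IKAROS RNP in PBS kept their call in every setting.

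The counts of called genes were 725 with the level filter and 608 by DESeq2 for the IKAROS RNP in PBS (1099), 1201 by DESeq2 for the IKAROS RNP in doxycycline (2063), and 29 by DESeq2 and 105 after GC correction for the interaction (46). The correlation between the inductions (0.673) was 0.884 with the level filter, where fewer genes are tested. The overlap (444) was 252 by DESeq2 and 1437 between averages over both backgrounds, which use all libraries. For GFI1 induction in control-RNP cells 7 lists were called, 2 with an estimated correlation and 13 with fry, which compares no list with other genes. The number was 5 with GC correction and an estimated correlation. For the IKAROS RNP in PBS 5 lists became 1 and 10, and 0 with GC correction and an estimated correlation. For the interaction 5 lists became 1 and 1, and 0 with GC correction and an estimated correlation. Apart from these constructions the cause was not tested.

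Without 1 library at a time, the counts ran from 2364 to 3478 for GFI1 induction in control-RNP cells, 449 to 1158 for the IKAROS RNP in PBS, 2454 to 4145 for GFI1 induction in IKAROS-RNP cells, 1390 to 2344 for the IKAROS RNP in doxycycline and 13 to 64 for the interaction. The correlation ran from 0.529 to 0.658 and the overlap from 223 to 522, both lowest without PBS IKAROS-RNP replicate 2, which leaves that group 1 library assumed to vary like the others. Called lists ran from 5 to 8, 3 to 6 and 3 to 5.

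After removal of group means, libraries of different groups with the same replicate number had correlations of -0.022 to 0.051. Those with different numbers had correlations of -0.057 to 0.043. These values do not settle whether the replicate numbers pair the samples. With the replicate number as a block, the counts were 3606, 1295, 4098, 2410 and 80, each above its value without the block. The overlap was 587, the correlation 0.671, and the called lists 7, 4 and 5. Pseudocounts and floors for normalized values do not apply to these counts. Thinned to the smallest total, the inductions gave 3022 and 3616 calls and the interaction 38.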

Other observations

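The test of the chromosome arm was chosen before its result was seen.

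Under GFI1 induction in control-RNP cells PRF1, which encodes perforin, rose by a log2 fold change of 3.86 ± 0.20 (SE), from 0.587 to 8.97 CPM, within a list of NK and cytotoxic markers where 3 of 7 tested genes rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.141). NKG7 in that list fell by 0.53 ± 0.08. Of 23 genes of IL7, cytokine and JAK-STAT signalling 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.536), with SOCS3 up by 1.36 ± 0.28. Of 16 BCL2 family genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.628): the cell death gene BMF rose by 2.34 ± 0.21 and PMAIP1 fell by 0.30 ± 0.05. Of 23 p53 targets 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.911), with BTG2 up by 0.42 ± 0.06. Of 24 reported IKAROS targets 8 rose and 5 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.837).

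Of 26 interferon response genes 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.781), with MX1 up by 0.35 ± 0.06. Immediate early and heat shock genes had 1 riser, NR4A1 at 0.66 ± 0.15, and 1 faller among 18 (1 and 1 adjusted over the list alone; camera adjusted p = 0.874). Of 24 corepressor genes 3 rose, including CHD4 by 0.14 ± 0.04 (3 adjusted over the list alone; camera adjusted p = 0.513), and of 26 DNA replication genes 3 fell, including MCM3 by 0.16 ± 0.03 (3 adjusted over the list alone; camera adjusted p = 0.186). Of 13 mitochondrially encoded genes 8 fell, including MT-CO1 by 0.21 ± 0.03, and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.141). Few markers of other blood or tissue cells were measurable: 8 B cell genes (2 rose, CD72 by 0.70 ± 0.07; camera adjusted p = 0.671), 4 myeloid genes (0 called by edgeR, CTSG at 0.07 and CEBPE at -0.04; camera adjusted p = 0.628), 4 erythroid and megakaryocyte genes (1 fell, TFRC by 0.14 ± 0.03; camera adjusted p = 0.837) and 4 fibroblast and endothelial genes (2 rose and 1 fell, PECAM1 by 0.23 ± 0.04; camera adjusted p = 0.874). Adjusted over each list alone these counts were 2, 0, 1 and 3, in the same directions.

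With the IKAROS RNP in PBS, GZMA, a granzyme gene, rose by 1.64 ± 0.19 from 1.47 CPM and GZMM fell by 0.52 ± 0.09. JUN rose by 0.45 ± 0.05, and among 26 interferon response genes 1 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.355), with HERC5 down by 0.34 ± 0.06 and MX1 down by 0.43 ± 0.08. Of 4 myeloid genes 1 rose, CTSG by 0.46 ± 0.07 (1 adjusted over the list alone; camera adjusted p = 0.196).

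IKZF1 lies on 7p, and a break there could remove the arm beyond it in some cells. The 141 tested protein-coding genes between IKZF1 and the 7p telomere had median log2 fold changes of -0.0095 in PBS and -0.0131 in doxycycline. Overlapping blocks of as many neighbouring genes elsewhere ran from -0.0211 to 0.0386 and from -0.0202 to 0.0282 (central 95% of 733 blocks), so these values argue against loss of the arm in a large share of cells.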
